A study of Mus musculus with 12 samples.

How the data were processed

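RNA was sequenced from the neurite and soma compartments of mouse dorsal root ganglion (DRG) neuron cultures, grown for 3 days on porous inserts with 1 µm pores from the ganglia of 1 adult mouse per culture. Per the labels, the cultures were GAR+/- (het below) or GAR+/+ (WT), and there were 3 libraries for each of the 4 combinations of genotype and compartment, 12 in all. Per the extraction protocol in the labels, total RNA was depleted of ribosomal RNA and made into stranded libraries. Per the submitters' processing notes, CASAVA 1.8.2 and edgeR were used with the mm10 (GRCm38) genome. The aligner and the counting program are not given in the sources used here.

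The authors deposited a table per compartment, each with 1 row per Ensembl transcript and 6 libraries. Per the file headers and the values, the deposited per-library columns hold raw counts, whole numbers that sum to a different total in each library. Per the file headers, the authors also deposited log2 fold changes of het over WT from their own edgeR comparison in each compartment. Per the file headers, a p-value and a false discovery rate came with each of the authors' comparisons, and the edgeR test behind them is not stated. The soma table held 35313 transcripts under 17678 gene names and that of the neurites held 32838 transcripts under 16872 gene names. All transcripts of both tables had at least 5 counts in at least 3 of the 6 libraries, so low transcripts had been removed in each compartment separately. In each library, between 0.57% and 0.69% of the counts belonged to transcripts without a gene name. The remaining 24 per-sample columns of the tables were not used here.

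Counts were summed per gene name over the 31420 named transcripts present in both tables, which gave 16617 genes. A further 1043 genes were named in the soma table alone and 237 in the neurite table alone, and these were left out of the comparisons because the counts of the other compartment were not analysed here. Of the 36285 transcripts in both tables together, 97.61% were found by identifier in GENCODE M21, from which gene identifiers and GRCm38 positions were taken. No mitochondrially encoded transcript was in the tables.

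Genes were filtered with filterByExpr, scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with a robust quasi-likelihood model, 1 mean per group and a spread shared by all 12 libraries, which left 15990 genes. There were 5 contrasts: neurites against soma in WT, neurites against soma in het, het against WT in soma, het against WT in neurites, and the interaction, which is the het neurite-to-soma change minus the WT neurite-to-soma change. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each contrast, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. Levels are CPM, counts scaled to the TMM-adjusted library size, as mean ± SD with n = 3 libraries per group. All tests were 2-sided.

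Before the data were examined, 29 gene lists, the contrasts, the alternatives and the rule for named genes were fixed. Of these lists, 27 had at least 5 tested members. Of the other lists, the blood list had only Pf4 among the tested genes and the list of mitochondrially encoded mRNAs had none. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27 lists, and again with an estimated correlation and with fry. For each list, the number of members past the threshold over all genes is given, and the number adjusted over the list alone. The lists of cell types hold genes that neurons may share, and some genes stand in several lists, such as Egr2 (immediate early genes and Schwann cells), Scn1a (large-diameter sensory neurons and channels) and Thy1 (pan-neuronal genes and fibroblasts).

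The genes named in each comparison are Ncl, Kpnb1 and Mtor in every case, and of the genes past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, up to 6 with the highest and up to 6 with the lowest log2 fold change. Predicted genes, pseudogenes and small RNAs were counted but not named. Where no gene passed, the 3 genes with the smallest p in each direction are named. Up to 4 members of a list with the smallest p are named, and at most 2 where no member passed. Outside this rule stand only the members of a list of RNAs described at cell protrusions and the nuclear RNAs used in a test of the neurite fraction, both chosen after the values were seen.

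Totals per library ranged from 14965973 to 32434916 counts. An observed count of 0 is compatible with a true mean of up to 3 counts, which corresponded to 0.0905 to 0.21 CPM, and this covers counting error only. The biological coefficient of variation was 0.143 in WT soma, 0.12 in het soma, 0.214 in WT neurites, 0.171 in het neurites and 0.163 over all groups. The fit was tested on simulated data with the same depths and spread. Of 100 genes changed 2-fold, between 91 and 100 were recovered in the 2-group comparisons and 66 in the interaction. Between 5.1% and 9.9% of the calls were false. The changed genes had an average level above 10 CPM, and each gene and library was drawn independently, without pairs of libraries or correlation between genes. These rates hold for such data only, and changes in genes at lower levels were not simulated. After scaling, the median log2 fold change over all genes lay between -0.0165 and 0.0086 in the 5 contrasts.

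The replicate numbers were tested as pairs by correlating the deviations of equally numbered libraries from their group means. With a minimum correlation of 0.1 in all 3 pairs set in advance, the numbers paired neurites with soma in WT (0.28, 0.34 and 0.23) and het with WT in soma (0.22, 0.27 and 0.16), and for these a fit with the replicate number as a block is given beside the main result. In het, neurites and soma missed that minimum in 1 pair (0.2, 0.26 and 0.05), though each library correlated best with its own number. Both sides of an insert hold 1 culture, but the labels do not state that equal numbers mark it, so the blocked values are given in het as well. The lowest pair was -0.04 for het with WT in neurites, and that comparison was not treated as paired. Blocked fits of neurites with soma used all 12 libraries, and those of het with WT used the 6 libraries of the compartment alone.

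Alternatives fixed in advance were DESeq2 size factors, no filter, a filter of at least 1 CPM in all libraries of a group, a DESeq2 1.42.0 Wald test, a fit of the compared libraries alone, the replicate block and leaving out each library in turn. A count per transcript in place of a sum per gene, and limma voom with a weight per group, were added after the data were seen. All 10 splits of the 6 libraries of each comparison into 3 and 3 were also fitted. Python 3.11.15 with matplotlib 3.10.9 drew the plots.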

Results

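The series compared RNA in the neurites and the cell bodies (soma) of cultured adult mouse DRG neurons, labelled GAR+/+ (WT) or GAR+/- (het), and concerned nucleolin, an RNA-binding protein of the nucleolus that also occurs in the cytoplasm. GAR names the glycine- and arginine-rich domain of nucleolin, and the het cultures were heterozygous at it. In modified Boyden chambers, neurites grow through the pores of a membrane and the soma stay above it, so that each side can be lysed separately. Ribosomal RNA was depleted before the libraries were made. There were 3 libraries of WT soma (25191686, 26335219 and 22232250 counts) and 3 of het soma (32434916, 25917161 and 22163752). There were also 3 of WT neurites (14965973, 15815820 and 25915003) and 3 of het neurites (18793693, 26797243 and 23339223). The labels state 3 independent biological repeats and 1 mouse per culture. The p-values of single genes measure the spread between libraries of these cultures, and the main fit did not pair neurites with soma. Those of camera at the preset correlation set a list against the other genes with that correlation held fixed, so they are not a measure of that spread. The estimated correlation ran from -0.0409 for sex-linked genes to 0.704 for proliferation genes, against the preset 0.01.

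Nucleolin mRNA itself was measured in every library. Ncl (ENSMUSG00000026234.12, chromosome 1, 86344719 to 86359400 on the minus strand of GRCm38) stood at 231 ± 12.1 CPM in WT soma and 266 ± 21.1 CPM in het soma (mean ± SD, n = 3 each). The levels were 400 ± 72.1 CPM in WT neurites and 380 ± 46.9 CPM in het neurites. Het over WT, the log2 fold change of Ncl was 0.20 ± 0.13 (SE) in soma, with an adjusted p of 0.697, and -0.07 ± 0.13 in neurites, with an adjusted p of 0.794. The tables count 1 transcript of Ncl as a whole, so they do not show which domain a transcript codes for.

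**Figure D1:**
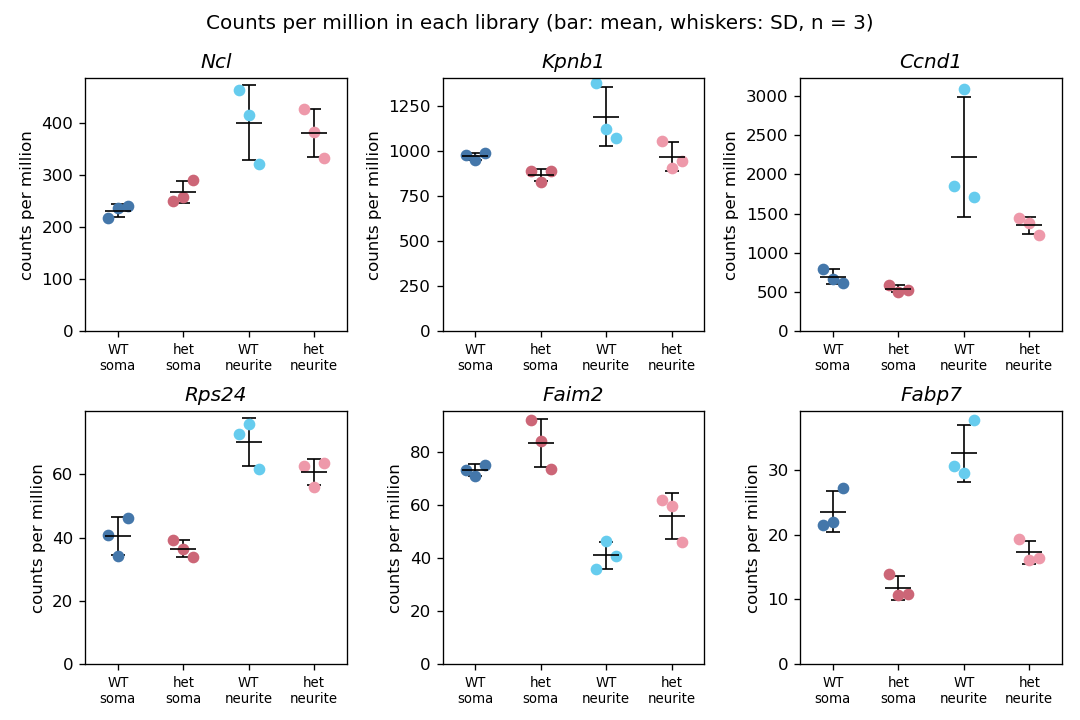
CPM in each of the 12 libraries for Ncl, Kpnb1, Ccnd1, Rps24, Faim2 and Fabp7, with the mean and SD of each group (n = 3). Ccnd1 and Rps24 lie higher in the neurite libraries of both genotypes, and Fabp7 lies lower in the het libraries of both compartments. Faim2 lies lower in the neurite libraries of WT. In het neurites against soma it had a log2 fold change of -0.58 ± 0.11 (SE) in the edgeR fit with the replicate block (adjusted p = 0.00527).

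The comparison of WT neurites with WT soma asked which RNAs differ between the compartments in GAR+/+ cultures. Nes, an intermediate filament gene of progenitor and glial cells, rose 4.07-fold in neurites (log2 fold change 2.02 ± 0.29 SE, adjusted p = 0.00676), from 83.8 ± 18.1 to 341 ± 141 CPM (mean ± SD, n = 3 each). Ccnd1, which codes for the cell cycle protein cyclin D1, rose 3.18-fold (1.67 ± 0.19, adjusted p = 0.00284), from 698 ± 92.4 to 2220 ± 761 CPM. Ncl rose 1.73-fold (0.79 ± 0.13, adjusted p = 0.00581). Faim2, a neuronal survival gene, fell 1.78-fold from 73.2 ± 2.25 to 41.1 ± 5.19 CPM (log2 fold change -0.83 ± 0.13, adjusted p = 0.0051). In total, 495 of 15990 genes passed the threshold, 385 higher and 110 lower in neurites. Which cells the RNA of the neurite fraction came from was not measured, so a rise there is not shown to lie in axons.

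The other genes with the highest fold changes in WT neurites were Cdc42bpg, a kinase downstream of the GTPase Cdc42 (3.96-fold), Sh3pxd2a, a scaffold of invasive cell protrusions (2.91-fold), Rab13, a small GTPase (2.72-fold), and Tns3, a tensin of focal adhesions (2.66-fold). Their adjusted p-values were 0.0095, 0.00625, 0.00452 and 0.00463. Others with the lowest were the neuronal adhesion gene Cntn1 (1.88-fold lower), Adam11 (1.82-fold lower), the potassium channel partner Kcnip3 (1.81-fold lower), the synaptic vesicle gene Sv2b (1.81-fold lower) and Lgi3 (1.77-fold lower). Their adjusted p-values were 0.0272, 0.0185, 0.00393, 0.0288 and 0.0196.

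Of the gene lists, 14 passed camera at the preset correlation in WT, and none of them with an estimated correlation. Cytosolic ribosomal protein mRNAs rose in neurites with a median log2 fold change of 0.14 (14 of 86 members passed, 20 adjusted over the list alone, adjusted p = 2.62e-06, and adjusted p = 0.561 with an estimated correlation). Among them, Rps24 rose 1.73-fold and Rpl39 1.61-fold. Nucleolar and ribosome biogenesis mRNAs had a median of 0.27 (5 of 46 rose, 14 adjusted over the list alone, adjusted p = 2.84e-06, and adjusted p = 0.326 with an estimated correlation). The members Ncl, Ddx21 (1.5-fold) and Bms1 (1.39-fold) passed. Translation factors had a median of 0.11 (6 of 72 rose, 8 higher and 1 lower adjusted over the list alone, adjusted p = 0.00049, and adjusted p = 0.326 with an estimated correlation). Eif3a rose 1.66-fold and Pabpc1 1.57-fold.

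Lists of neurons lay lower in WT neurites. The median log2 fold change of sodium and potassium channel mRNAs was -0.45 (3 of 35 fell, 25 adjusted over the list alone, adjusted p = 1.69e-12, and adjusted p = 0.326 with an estimated correlation). The pan-neuronal and cytoskeletal list had a median of -0.30 (2 of 36 fell, 9 adjusted over the list alone, adjusted p = 1.9e-08, and adjusted p = 0.395 with an estimated correlation). Nociceptor genes had a median of -0.38 (2 of 27 fell, 7 adjusted over the list alone, adjusted p = 1.26e-08, and adjusted p = 0.189 with an estimated correlation). Large-diameter neuron genes had -0.43 (2 of 20 fell, 7 adjusted over the list alone, adjusted p = 6.18e-06, and adjusted p = 0.326 with an estimated correlation). Members that fell included Rbfox3 (1.52-fold), Uchl1 (1.37-fold), Calca, the gene of the peptide CGRP (1.54-fold), and Scn1a (1.87-fold). Nucleus-retained long RNAs had a median of -0.62 (1 of 9 fell, Rian by 1.65-fold, 2 adjusted over the list alone, adjusted p = 0.00507, and adjusted p = 0.561 with an estimated correlation). Small nucleolar RNAs (snoRNA) had a median of -0.245 (0 of 46 passed, 0 adjusted over the list alone, adjusted p = 0.00935, and adjusted p = 0.591 with an estimated correlation). Without WT neurite library 1 the nuclear long RNAs no longer passed (adjusted p = 0.0541), nor did snoRNA without WT neurite library 2 (adjusted p = 0.495).

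Lists of other cell types moved with these groups. In WT neurites, satellite glia genes had a median of 0.54 (1 of 20 rose and 1 fell, 11 and 1 adjusted over the list alone, adjusted p = 1.35e-05, and adjusted p = 0.326 with an estimated correlation). Schwann cell genes had 0.40 (2 of 23 rose and 1 fell, 9 and 3 adjusted over the list alone, adjusted p = 0.00028, and adjusted p = 0.326 with an estimated correlation). Proliferation genes had 0.56 (0 of 33 passed, 0 adjusted over the list alone, adjusted p = 3.44e-06, and adjusted p = 0.561 with an estimated correlation). The transcription factors Sox2 (1.46-fold) and Sox10 (1.42-fold) and the myelin gene Prx (2.21-fold) rose, while the neurotrophin receptor gene Ngfr (1.44-fold) and Pla2g7 (1.44-fold) fell. Immediate early genes had a median of 0.31 (1 of 19 rose, Nr4a1 by 1.6-fold, 2 adjusted over the list alone, adjusted p = 0.0225, and adjusted p = 0.561 with an estimated correlation). That call was lost without WT soma library 1 (adjusted p = 0.0983), WT soma library 2 (0.0638) or WT neurite library 3 (0.156). Macrophage and leukocyte genes had a median of -0.36 (0 of 18 passed, 0 adjusted over the list alone, adjusted p = 0.00935, and adjusted p = 0.591 with an estimated correlation). Theirs was lost without WT neurite library 1 (adjusted p = 0.129).

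The remaining lists did not pass in WT. Their median log2 fold changes were 0.000166 for nuclear oxidative phosphorylation (mean -0.01), 0.08 for replication-dependent histones, -0.10 for mRNAs described in axons, 0.06 for mRNAs described as nucleolin-bound and 0.07 for nuclear transport and dynein. They were -0.06 for mTOR signalling, 0.11 for cholesterol biosynthesis, -0.17 for neuronal injury and regeneration and 0.28 for fibroblasts and matrix. The last were 0.36 for endothelium, pericytes and muscle, 0.35 for the type I interferon response, -0.02 for unfolded protein and p53 stress (mean 0.02) and 0.11 for sex-linked genes. Single members passed in some of them. In the axon list, Vim, an intermediate filament gene, rose 1.67-fold and Pard3, a polarity gene, 1.8-fold (2 of 34, and 3 higher and 1 lower adjusted over the list alone). Bcl2, a survival gene, rose 1.49-fold in the nucleolin-bound list (1 of 10, and 1 adjusted over the list alone). Kpnb1, the gene of importin β1, had a log2 fold change of 0.29 ± 0.11 (adjusted p = 0.152) and Mtor, the gene of a growth-regulating kinase, -0.18 ± 0.10 (adjusted p = 0.369). The blood gene Pf4 had -0.48 ± 0.81 (adjusted p = 0.793). Without WT neurite library 3, the histone list passed in the other direction, with a median of -0.11 and an adjusted p of 0.0183.

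With the replicate number as a block, 1489 genes passed in WT (936 higher and 553 lower in neurites). There Ncl had a log2 fold change of 0.77 ± 0.13 (adjusted p = 0.00124), Nes 1.97 ± 0.33 (0.0259), Ccnd1 1.62 ± 0.15 (1.96e-05) and Faim2 -0.84 ± 0.11 (0.000274). The blocked fit gave a median of 0.14 for ribosomal proteins (20 rose, adjusted p = 1.18e-05), -0.46 for channels (19 fell, 6.06e-15), 0.54 for proliferation genes (15 rose, 2.8e-11) and 0.515 for satellite glia (6 rose, 1 fell, 1.61e-07). It added the lists of neuronal injury (-0.13, 0.0222), endothelium (0.32, 0.00696) and interferon (0.31, 0.000905). With an estimated correlation none of these 7 passed in the blocked fit (adjusted p = 0.372 for ribosomal proteins, 0.303 for channels, proliferation and injury, 0.321 for satellite glia and interferon, and 0.332 for endothelium). The count of 495 became 105 without WT soma library 1, 93 without WT soma library 2, 250 without WT soma library 3, 172 without WT neurite library 1 and 1081 without WT neurite library 2. It was 40 in a fit of the 6 WT libraries alone, 329 with limma voom and 1123 with a DESeq2 Wald test. Of the 12 genes named for their fold change, 7 passed with any library left out (Nes, Ccnd1, Sh3pxd2a, Rab13, Tns3, Kcnip3 and Faim2), as did Ncl. In the fit of the WT libraries alone, Ncl (adjusted p = 0.0531), Nes (0.0529) and Sh3pxd2a (0.0679) of these did not pass. Cdc42bpg did not pass without WT soma library 1 or 2 (highest adjusted p 0.0636), nor Adam11 without either of these or WT neurite library 1 (0.0843). Cntn1 (0.107) and Lgi3 (0.0837) did not pass without any 1 of WT soma libraries 1 and 2 and WT neurite libraries 1 and 3, and Sv2b passed only without WT neurite library 2 (highest adjusted p 0.114 in the other 5 fits).

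The comparison of het neurites with het soma asked the same of the GAR+/- cultures. Cdc42bpg rose 3.15-fold in het neurites (log2 fold change 1.66 ± 0.30 SE, adjusted p = 0.0468), from 26.2 ± 4.28 to 82.6 ± 16.7 CPM (mean ± SD, n = 3 each). Nes rose 2.86-fold (1.52 ± 0.28, adjusted p = 0.0487), from 57.8 ± 11.7 to 165 ± 31 CPM, and Ccnd1 rose 2.5-fold (1.32 ± 0.19, adjusted p = 0.0202), from 541 ± 44.3 to 1350 ± 113 CPM. The nicotinic receptor gene Chrna7 fell 1.74-fold from 91.2 ± 5.45 to 52.4 ± 10.2 CPM (-0.80 ± 0.15, adjusted p = 0.0343). In total 102 genes passed, 87 higher and 15 lower in neurites.

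Sytl2, a Rab effector of vesicle transport (2.59-fold), Tns3 (2.43-fold) and Trak2, an adaptor of kinesin and mitochondria (2.42-fold), were also among the highest, with adjusted p-values of 0.0379, 0.0215 and 0.0468. Also among the lowest were the matrix gene Hapln1 (1.9-fold lower), Prrt3 (1.88-fold lower), the growth factor gene Hgf (1.74-fold lower) and the synaptic adhesion gene Igsf21 (1.68-fold lower), with adjusted p-values of 0.0381, 0.0215, 0.0384 and 0.0468. Ncl had a log2 fold change of 0.51 ± 0.13 (adjusted p = 0.0887), Kpnb1 0.16 ± 0.11 (adjusted p = 0.562) and Mtor -0.25 ± 0.10 (adjusted p = 0.293).

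Of the lists, 13 passed in het at the preset correlation and none with an estimated correlation. Ribosomal protein mRNAs rose with a median of 0.24 (15 of 86 passed, 29 adjusted over the list alone, adjusted p = 3.78e-14, and adjusted p = 0.408 with an estimated correlation), among them Rpl39 (1.79-fold), Rps24 (1.66-fold) and Rps26 (1.5-fold). Nuclear oxidative phosphorylation mRNAs had a median of 0.11 (1 of 74 rose, Ndufb9 by 1.37-fold, 1 adjusted over the list alone, adjusted p = 0.000219, and adjusted p = 0.697 with an estimated correlation), and without het neurite library 3 that call was lost (adjusted p = 0.32). Translation factors had a median of 0.13 (2 of 72 rose, Eif5b by 1.44-fold and Pabpc1 by 1.41-fold, 6 adjusted over the list alone, adjusted p = 0.00011, and adjusted p = 0.408 with an estimated correlation). Nucleolar mRNAs had a median of 0.18 (0 of 46 passed, 0 adjusted over the list alone, adjusted p = 1.23e-05, and adjusted p = 0.411 with an estimated correlation). Channels had a median of -0.42 (2 of 35 fell, including Kcnh2 by 1.61-fold, 21 adjusted over the list alone, adjusted p = 3.22e-15, and adjusted p = 0.408 with an estimated correlation). Nociceptor genes had -0.33 (1 of 27 fell, 2 adjusted over the list alone, adjusted p = 2.42e-06, and adjusted p = 0.408 with an estimated correlation).

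In het, large-diameter neuron genes had a median of -0.37 (0 of 20 passed, 3 lower adjusted over the list alone, adjusted p = 7.61e-06, and adjusted p = 0.408 with an estimated correlation) and pan-neuronal genes one of -0.16 (0 of 36 passed, 0 adjusted over the list alone, adjusted p = 0.000141, and adjusted p = 0.697 with an estimated correlation). The median was -0.54 for snoRNA (0 of 46 passed, 0 adjusted over the list alone, adjusted p = 9.16e-05, and adjusted p = 0.697 with an estimated correlation). It was -0.32 for nuclear long RNAs (0 of 9 passed, 1 lower adjusted over the list alone, adjusted p = 0.0341, and adjusted p = 0.72 with an estimated correlation). These passed neither without het soma library 1 (adjusted p = 0.153) nor without het neurite library 3 (0.619). Genes of other cells moved here too. Satellite glia had a median of 0.36 (0 of 20 passed, 2 higher and 1 lower adjusted over the list alone, adjusted p = 0.00169, and adjusted p = 0.681 with an estimated correlation) and proliferation genes one of 0.39 (0 of 33 passed, 0 adjusted over the list alone, adjusted p = 2.14e-05, and adjusted p = 0.697 with an estimated correlation). Macrophage genes had -0.46 (0 of 18 passed, 0 adjusted over the list alone, adjusted p = 0.00799, and adjusted p = 0.744 with an estimated correlation). The satellite glia call was lost without het neurite library 1 (adjusted p = 0.106) and the macrophage call without het neurite library 1 (0.62), het neurite library 2 (0.0728) or het soma library 3 (0.506, with a median of 0.04). Schwann cell genes had a median of 0.22 (adjusted p = 0.0517).

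With the replicate number as a block, 671 genes passed in het (407 higher and 264 lower in neurites). There Ncl rose in neurites, with a log2 fold change of 0.51 ± 0.13 (adjusted p = 0.0298). Ccnd1 had 1.32 ± 0.15 (0.000328) and Chrna7 -0.81 ± 0.12 (0.00153), while Nes (1.52 ± 0.33, 0.0784) and Cdc42bpg (1.65 ± 0.31, 0.0523) did not pass. The block added Schwann cells (0.21, adjusted p = 0.0253, and 0.61 with an estimated correlation) and interferon (0.18, adjusted p = 0.0109, and 0.456 with an estimated correlation).

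Of the 87 genes higher in het neurites, 75 were also among the 385 higher in WT neurites, against 2.1 for independent calls, and 11 of the 15 lower genes were among the 110 lower in WT. Across all genes the neurite-to-soma changes of both genotypes had a Pearson correlation of 0.50, and of 0.77 among genes above the median level; genes are not independent replicates. The count of 102 became 0 without het soma library 1, het soma library 2 or het neurite library 1, 1 without het soma library 3, 24 without het neurite library 3 and 191 without het neurite library 2. It was 482 with a DESeq2 Wald test and 223 with limma voom. None of the genes named for their fold change passed with every library left out in turn, and their log2 fold changes kept their sign in those fits. The highest adjusted p in these fits was 0.162 for Ccnd1, 0.168 for Chrna7, 0.222 for Cdc42bpg and 0.243 for Nes.

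**Figure D2:**
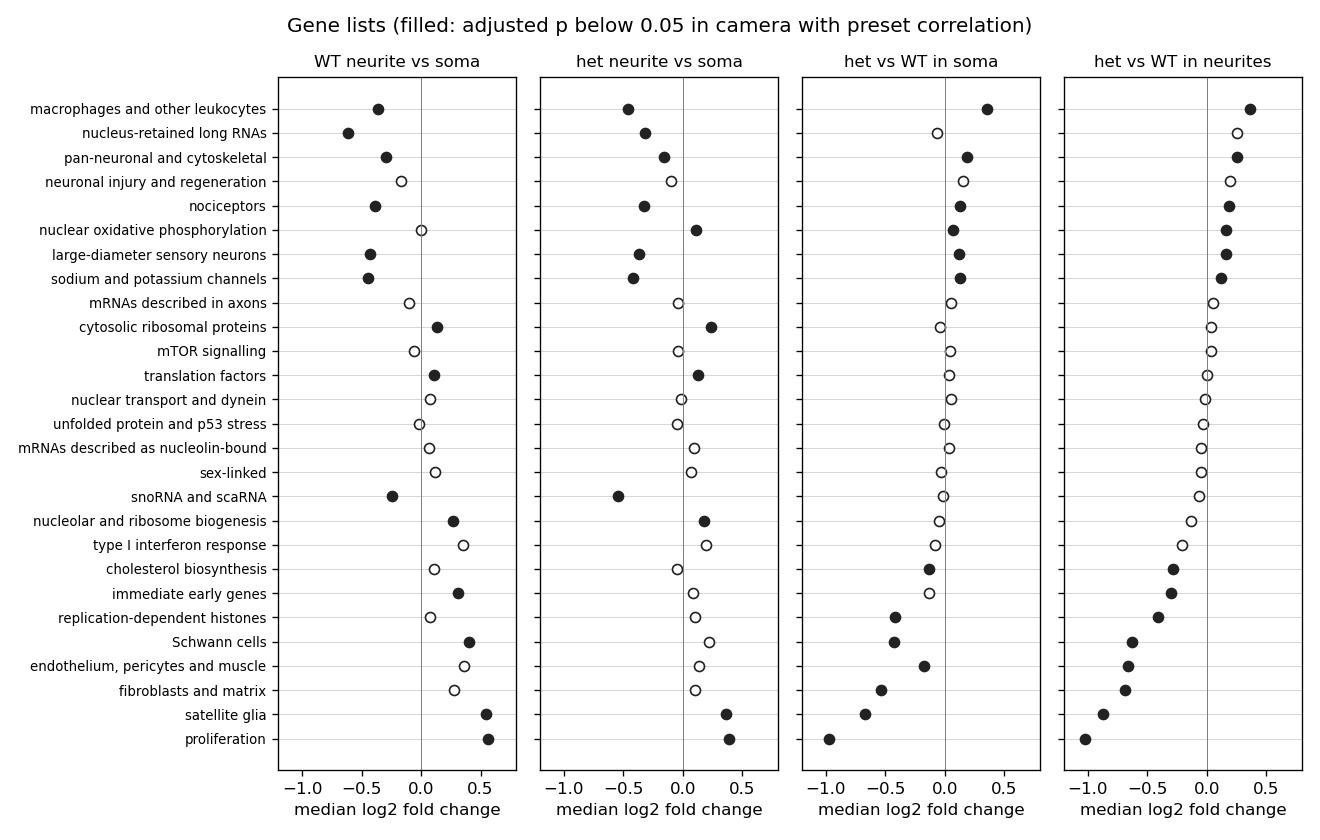
Median log2 fold change of the 27 tested gene lists in 4 comparisons; filled points have an adjusted p below 0.05 in camera at the preset correlation. Channel and neuron lists lie left of 0 in both neurite-to-soma panels, and proliferation and satellite glia lists lie far left of 0 in both het-to-WT panels.

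The comparison of het with WT soma asked which RNAs differ with the GAR genotype in the cell bodies. No gene passed in the edgeR quasi-likelihood fit of all 12 libraries: 0 of 15990 at the adjusted threshold and 1464 at an unadjusted p under 0.05, where chance gives 800. The count was 388 in a fit of the 6 soma libraries alone. With the replicate block added to that fit of 6 libraries, it was 1300 (244 higher and 1056 lower in het). It was 322 with a DESeq2 Wald test, 259 with limma voom and 19 per transcript. Fabp7 (ENSMUSG00000019874.11, chromosome 10, 57784881 to 57788450 on the plus strand), a fatty acid binding gene of glia, stood at 23.5 ± 3.12 CPM in WT and 11.8 ± 1.88 CPM in het soma (mean ± SD, n = 3 each). Its log2 fold change was -0.99 ± 0.15 (SE) with an adjusted p of 0.0635 (blocked -0.99 ± 0.13, 0.000152). Ncapd2, a condensin gene needed for mitosis, stood at 89.5 ± 8.16 and 49.7 ± 3.69 CPM, -0.85 ± 0.14 with an adjusted p of 0.082 (blocked -0.85 ± 0.08, 6.16e-06).

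Mmd2 had a log2 fold change of -0.93 ± 0.14 (adjusted p = 0.0635, blocked 0.000553). In the other direction, Mpped2 had 0.51 ± 0.13 (adjusted p = 0.144, blocked 0.011), Cabp1, a neuronal calcium-binding gene, 0.48 ± 0.13 (adjusted p = 0.172, blocked 0.001) and Gpx3, a secreted glutathione peroxidase gene, 0.71 ± 0.20 (adjusted p = 0.18, blocked 0.00105). Kpnb1 had -0.16 ± 0.11 (adjusted p = 0.71, blocked 0.228) and Mtor 0.04 ± 0.10 (adjusted p = 0.935, blocked 0.788). Blocked, Ncl had 0.20 ± 0.07 (adjusted p = 0.105).

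As a group, proliferation genes fell in het soma, with a median of -0.97 and all 33 members below 0 (0 passed over all genes, 28 adjusted over the list alone, adjusted p = 9.28e-28, and adjusted p = 0.387 with an estimated correlation). In the blocked fit the median was -0.98 and 28 members passed (adjusted p = 6.16e-35, and adjusted p = 0.408 with an estimated correlation). Satellite glia genes had a median of -0.67 (8 of 20 lower adjusted over the list alone, adjusted p = 4.41e-10, and adjusted p = 0.387 with an estimated correlation). Of these, Bcan, a proteoglycan gene, had -1.07 ± 0.23 (adjusted p = 0.111, blocked 3.87e-05). Schwann cell genes had a median of -0.43 (9 of 23 lower adjusted over the list alone, adjusted p = 1.43e-05, and adjusted p = 0.39 with an estimated correlation) and replication-dependent histones -0.42 (16 of 59 lower adjusted over the list alone, adjusted p = 8.31e-13, and adjusted p = 0.644 with an estimated correlation). Fibroblast genes had -0.53 (1 of 28 lower adjusted over the list alone, adjusted p = 2.28e-05, and adjusted p = 0.644 with an estimated correlation). The blocked medians were -0.63 for satellite glia (11 fell, 1.26e-11), -0.40 for Schwann cells (10 fell, 3.26e-06), -0.40 for histones (19 fell, 2.97e-12) and -0.53 for fibroblasts (9 fell, 4.94e-11). Blocked, their adjusted p with an estimated correlation was 0.408, 0.408, 0.607 and 0.538.

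Further soma lists passed with smaller medians, and for each of them the adjusted p was 0.644 with an estimated correlation. The medians were 0.19 for pan-neuronal genes (adjusted p = 1.78e-05, blocked 3.62e-07), 0.07 for nuclear oxidative phosphorylation (0.0079, blocked 0.0126), 0.13 for channels (0.00473, blocked 0.000999) and 0.13 for nociceptors (0.0222, blocked 0.0175). They were 0.115 for large-diameter neurons (0.0339, blocked 0.0215), 0.35 for macrophages (0.0185, blocked 0.0016), -0.14 for cholesterol biosynthesis (0.0185, blocked 0.0161) and -0.18 for endothelium (0.0242, blocked 0.00286 with a median of -0.0875). No member of these lists passed over all genes, and 4 endothelial genes were lower adjusted over the list alone. In the blocked fit 8 endothelial genes and 1 cholesterol gene passed lower over all genes, and 4 nociceptor, 3 pan-neuronal, 2 channel and 1 macrophage gene passed higher. Without WT soma library 1 the macrophage call was lost (adjusted p = 0.324), and without WT soma library 2 those of cholesterol (0.141) and nociceptors (0.0795). Without WT soma library 3, endothelium (0.465, with a median of 0.14), large-diameter neurons (0.313), nociceptors (0.11) and channels (0.207) were lost. Without het soma library 1 large-diameter neurons (0.0563) and oxidative phosphorylation (0.0843) were lost, and large-diameter neurons also with the filter of at least 1 CPM (0.0886). Without het soma library 2, cholesterol (0.283), endothelium (0.112), large-diameter neurons (0.181) and oxidative phosphorylation (0.0752) were lost, and without het soma library 3 macrophages (0.947, with a median of -0.07) and nociceptors (0.199). The interferon list had a median of -0.08 (adjusted p = 0.71) and without WT soma library 3 one of 0.32 (0.0354). The block added neuronal injury (0.16, adjusted p = 0.0402, and 0.749 with an estimated correlation) and immediate early genes (-0.14, adjusted p = 0.0428, and 0.607 with an estimated correlation). For the 8 lists above, the blocked adjusted p with an estimated correlation lay between 0.408 and 0.607.

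The comparison of het with WT neurites asked which RNAs differ with the GAR genotype in the neurite fraction. Which cells held these RNAs was not measured, so the differences are not shown to lie in axons. Satellite glia and proliferation genes lay higher in WT neurites than in WT soma (median log2 fold changes of 0.54 and 0.56), though neither list passed with an estimated correlation. Wnt6 (ENSMUSG00000033227.7, chromosome 1, 74771892 to 74785322 on the plus strand), a secreted signalling gene, fell 3.09-fold from 22.8 ± 5.51 to 7.43 ± 1.67 CPM (mean ± SD, n = 3 each; log2 fold change -1.63 ± 0.21 SE, adjusted p = 0.0116). Top2a, the topoisomerase of dividing cells, fell 2.87-fold from 378 ± 124 to 132 ± 55.2 CPM (-1.52 ± 0.34, adjusted p = 0.0438), and Fabp7 fell 1.89-fold from 32.5 ± 4.42 to 17.3 ± 1.78 CPM (-0.92 ± 0.15, adjusted p = 0.0124). Mpped2 rose 1.73-fold from 8.24 ± 0.323 to 14.2 ± 0.238 CPM (0.79 ± 0.13, adjusted p = 0.0124), and the neuropeptide gene Cartpt rose 1.68-fold from 61.8 ± 14.3 to 104 ± 14.6 CPM (0.74 ± 0.16, adjusted p = 0.0272). In total 523 genes passed, 79 higher and 444 lower in het neurites.

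Also among the lowest in het neurites were the smooth muscle myosin gene Myh11 (3.26-fold lower), Iqgap3, a scaffold gene of proliferating cells (2.9-fold lower), and the mitotic kinesin gene Kif4 (2.85-fold lower), with adjusted p-values of 0.0243, 0.038 and 0.0124. Also among the highest were Samd12 (1.67-fold), the vesicle transport gene Rab33a (1.64-fold) and Fxyd2, a sodium pump subunit of sensory neurons (1.63-fold), with adjusted p-values of 0.0372, 0.0372 and 0.0241. Kpnb1 had a log2 fold change of -0.30 ± 0.11 (adjusted p = 0.138) and Mtor -0.03 ± 0.10 (adjusted p = 0.917). In the nucleolin-bound list, Bcl2 fell 1.28-fold (1 of 10, and 1 adjusted over the list alone, adjusted p = 0.0468), and the median was -0.04 (adjusted p = 0.474).

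By list, 14 passed in neurites at the preset correlation and none with an estimated correlation. Proliferation genes fell with a median of -1.02 and all 33 members below 0 (12 fell, 30 adjusted over the list alone, adjusted p = 1.36e-18, and adjusted p = 0.419 with an estimated correlation). Kif23 fell 2.57-fold and Mcm2 1.79-fold. Satellite glia genes had a median of -0.875 (7 of 20 fell, 14 adjusted over the list alone, adjusted p = 5.53e-09, and adjusted p = 0.348 with an estimated correlation). Among them were Bcan (2.58-fold) and Sox2 (1.51-fold). Schwann cell genes had a median of -0.62 (7 of 23 fell, 12 adjusted over the list alone, adjusted p = 3.29e-07, and adjusted p = 0.348 with an estimated correlation), among them Prx (2.13-fold), Egr2 (1.92-fold) and Sox10 (1.56-fold). Histones had a median of -0.41 (8 of 59 fell, 13 lower and 1 higher adjusted over the list alone, adjusted p = 8.5e-06, and adjusted p = 0.646 with an estimated correlation). Endothelium and muscle had -0.66 (3 of 21 fell, 6 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.419 with an estimated correlation). Fibroblasts had -0.68 (1 of 28 fell, Fap by 1.9-fold, 1 adjusted over the list alone, adjusted p = 0.000775, and adjusted p = 0.646 with an estimated correlation).

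Immediate early genes fell with a median of -0.30 (3 of 19 fell, 6 adjusted over the list alone, adjusted p = 0.00338, and adjusted p = 0.419 with an estimated correlation). These were Egr2, Nr4a1 (1.77-fold) and Klf4 (1.59-fold). Cholesterol biosynthesis had a median of -0.285 (0 of 22 passed, 4 lower adjusted over the list alone, adjusted p = 0.000128, and adjusted p = 0.419 with an estimated correlation). Neuronal lists lay higher, with a median of 0.25 for pan-neuronal genes (3 of 36 rose, 8 adjusted over the list alone, adjusted p = 3.65e-08, and adjusted p = 0.419 with an estimated correlation). The nociceptor median was 0.19 (1 of 27 rose, 7 adjusted over the list alone, adjusted p = 0.00114, and adjusted p = 0.419 with an estimated correlation). Stmn3 and Uchl1 each rose 1.38-fold and Calcb 1.5-fold. Nuclear oxidative phosphorylation had a median of 0.16 (1 of 74 rose, Atp5g1 by 1.54-fold, 0 adjusted over the list alone, adjusted p = 2.41e-07, and adjusted p = 0.419 with an estimated correlation).

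Further neurite medians were 0.16 for large-diameter neurons (1 of 20 rose, Vsnl1 by 1.52-fold, 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0297, and adjusted p = 0.646 with an estimated correlation) and 0.12 for channels (0 of 35 passed, 0 adjusted over the list alone, adjusted p = 0.0232, and adjusted p = 0.7 with an estimated correlation). Macrophage genes had 0.36 (0 of 18 passed, 0 adjusted over the list alone, adjusted p = 0.0403, and adjusted p = 0.7 with an estimated correlation). These 3 calls were lost without WT neurite library 1 (adjusted p = 0.0567, 0.0994 and 0.299) or WT neurite library 3 (0.24, 0.229 and 0.055). Large-diameter neurons and channels were also lost without het neurite library 2 (adjusted p = 0.396 and 0.801, channels with a median of -0.06) and macrophages without het neurite library 3 (0.931, with a median of -0.07) and with DESeq2 size factors (0.051). Ribosomal proteins had a median of 0.03 (adjusted p = 0.396) and nucleolar genes -0.13 (adjusted p = 0.146).

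The count of 523 genes became 50 without WT neurite library 1, 1767 without WT neurite library 2 and 1110 without het neurite library 1. It was 0 without WT neurite library 3, het neurite library 2, het neurite library 3 or in a fit of the 6 neurite libraries alone, 117 with limma voom and 1217 with a DESeq2 Wald test. No named gene passed with every library left out in turn, and in those fits Wnt6 kept log2 fold changes between -1.82 and -1.48 and Mpped2 between 0.77 and 0.82. The highest adjusted p in these fits was 0.0946 for Wnt6, 0.0967 for Mpped2, 0.138 for Cartpt and 0.183 for Top2a.

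Of the 444 genes lower in het neurites, 118 were among the 385 higher in WT neurites than in WT soma, against 10.7 for independent calls. Both comparisons use the same WT neurite libraries, and 10 simulations with no effect gave a correlation of -0.53 between the changes, against -0.67 measured. The het-to-WT changes in soma and neurites had a Pearson correlation across genes of 0.56, and of 0.81 among genes above the median level; other splits of the cultures gave 0 to 0.47. Of the genes past the threshold in the blocked soma fit, 356 of the 1056 lower were also lower in het neurites, against 30.2 for independent calls. Of the 244 higher, 28 were also higher. Soma and neurite libraries may come from the same cultures, as both sides of an insert hold 1 culture. A difference between these cultures could then appear in both compartments, so this overlap and the correlation of 0.56 are not a repeat in other cultures.

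**Figure D3:**
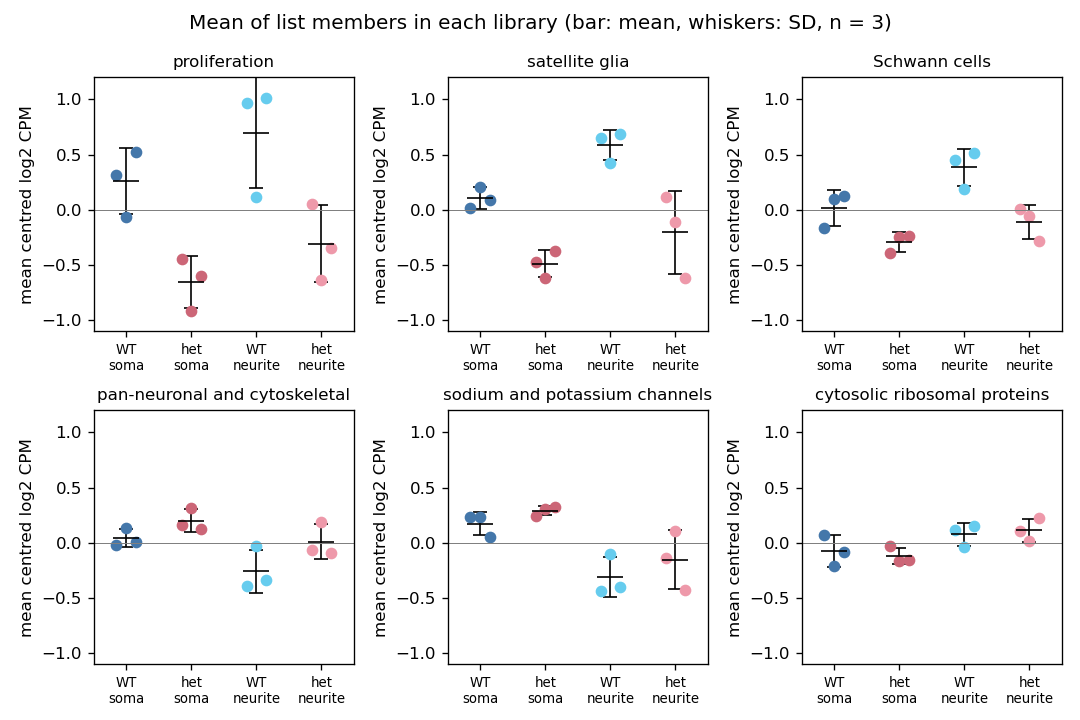
Mean centred log2 CPM of 6 gene lists in each of the 12 libraries, with group means. The proliferation score averages 0.26 in WT soma, -0.65 in het soma, 0.70 in WT neurites and -0.31 in het neurites, and the satellite glia score averages 0.11, -0.49, 0.59 and -0.20.

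The interaction asked whether the difference between neurites and soma itself depends on genotype. No gene passed in the edgeR quasi-likelihood fit (0 of 15990, 202 at an unadjusted p under 0.05 where chance gives 800). The counts of a DESeq2 Wald test, limma voom, the replicate block and all fits with a library left out were also 0. Small p-values were fewer than chance gives in the main fit, so 0 calls do not show that the difference was equal in both genotypes. Ncl had an interaction of -0.28 ± 0.18 on the log2 scale (SE, adjusted p = 1), Kpnb1 -0.13 ± 0.15 and Mtor -0.07 ± 0.15. The smallest p-values were those of the calcium sensor gene Vsnl1 (0.62 ± 0.20), the metallothionein gene Mt3 (0.43 ± 0.15), Bcdin3d (0.53 ± 0.19), the centriole gene Poc1a (-0.74 ± 0.24), the Polycomb gene Cbx2 (-0.44 ± 0.15) and Ppp1r12c (-0.49 ± 0.18), all with an adjusted p of 1. Of the lists, 8 passed at the preset correlation with medians between -0.178 and 0.115, and none did with an estimated correlation, where their adjusted p was 0.923 or 0.958. The count of 8 lists became 5, 6 and 13 without WT soma library 1, 2 and 3, and 5, 9 and 5 without het soma library 1, 2 and 3. It became 3, 13 and 5 without WT neurite library 1, 2 and 3, and 11, 6 and 7 without het neurite library 1, 2 and 3.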

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

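The length and GC test of the oxidative phosphorylation list was set up before its result was seen, and the comparison of that list with pan-neuronal genes and the length and GC test in the blocked fit were chosen after the result was seen.

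The neurite-to-soma difference of 8 gene lists differed between genotypes in camera at the preset correlation. That test was of the difference itself, from 3 cultures per genotype, and set each list against the other genes. The median interaction was 0.0659 for ribosomal proteins (62 of 86 members above 0, adjusted p = 0.0166), 0.109 for nuclear oxidative phosphorylation (54 of 74 above 0, 4.7e-05), 0.115 for pan-neuronal genes (29 of 36 above 0, 0.00182) and 0.0936 for nociceptors (18 of 27 above 0, 0.0444). It was -0.133 for cholesterol biosynthesis (19 of 22 below 0, 0.0116), -0.164 for immediate early genes (18 of 19 below 0, 0.0217), -0.146 for Schwann cells (19 of 23 below 0, 0.0116) and -0.178 for satellite glia (16 of 20 below 0, 0.0444). With an estimated correlation the adjusted p was 0.958 for ribosomal proteins and 0.923 for each of the others, and no gene passed on its own. With the replicate number as a block these 8 passed and endothelium was added (-0.227, adjusted p = 0.0163), and with an estimated correlation each of the 9 had an adjusted p of 0.731.

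Each of the 8 calls was lost when some library was left out. Ribosomal proteins were lost without WT soma library 1 (adjusted p = 0.833), het soma library 2 (0.113) or 3 (0.107), WT neurite library 2 (0.318) or het neurite library 3 (0.995, with a median of -0.017). Cholesterol biosynthesis was lost without WT soma library 1 (0.131), het soma library 1 (0.111) or 3 (0.0763), WT neurite library 1 (0.0624) or 3 (0.214), or het neurite library 2 (0.0927) or 3 (0.0728). Immediate early genes were lost without WT soma library 1 (0.239) or 2 (0.114), het soma library 3 (0.147), WT neurite library 1 (0.0946) or 3 (0.229), or het neurite library 2 (0.363). Pan-neuronal genes were lost without WT soma library 2 (0.122), WT neurite library 1 (0.311) or 3 (0.141), or het neurite library 2 (0.433). Nociceptors were lost without WT soma library 1 (0.322), het soma library 1 (0.285) or 2 (0.103), WT neurite library 1 (0.0783), 2 (0.104) or 3 (0.117), or het neurite library 2 (0.621, with a median of -0.05). Their adjusted p was 0.0507 without a filter and 0.126 with the filter of at least 1 CPM. Schwann cell genes were lost without WT soma library 1 (0.239), WT neurite library 3 (0.194) or het neurite library 3 (0.362). Satellite glia genes were lost without WT soma library 1 (0.335), het soma library 1 (0.0638) or 3 (0.147), WT neurite library 1 (0.104) or 3 (0.229), or het neurite library 3 (0.995, with a median of -0.0295). Oxidative phosphorylation was lost without het neurite library 3 alone (0.222, with a median of 0.04).

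Of these, the oxidative phosphorylation mRNAs had the smallest adjusted p. After the trend of the interaction on transcript length and GC content was removed, 47.4% of their median was left (0.109 before, 0.052 after), and 46.2% in the fit with the replicate number as a block, so such a trend stays open. Set against pan-neuronal genes within each pair of equally numbered libraries, their neurite-to-soma shift differed between genotypes by 0.04 pooled SD. Their shift alone differed by only 0.83 pooled SD, so this comparison could hardly have come out otherwise and decides nothing. From soma to neurites the pan-neuronal score moved by -0.3 in WT and -0.19 in het, and the oxidative phosphorylation score by -0.02 and 0.1. A different share of glial RNA in the WT and het neurite fractions stays open. No biological explanation was tested beyond the genotype itself.

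The authors' deposited statistics held 18 soma transcripts and 6 neurite transcripts past a false discovery rate of 0.05 that were listed in the table of that compartment alone. The comparisons above did not use these transcripts, and their counts in the other compartment were not analysed here.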

How the results depend on the processing

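The counts per transcript and the limma voom fits were chosen after the results were seen. Numbers of genes past the threshold moved between fits in the comparisons of 2 groups, and the cause was not tested. The main fit shared 1 spread over all 12 libraries. The biological coefficient of variation was 0.143 and 0.12 in WT and het soma, and 0.214 and 0.171 in WT and het neurites. For het against WT, the main fit called 0 genes in soma and 523 in neurites, and fits of the compared libraries alone 388 and 0. These counts therefore do not show in which compartment the genotypes differed more. A DESeq2 Wald test gave 1123 genes in WT neurites against soma, 482 in het, 322 in het against WT soma and 1217 in het against WT neurites. Fits of the compared libraries alone gave 40, 91, 388 and 0, and limma voom gave 329, 223, 259 and 117. Per transcript, 19 passed in het against WT soma. With DESeq2 size factors, no filter or the filter of at least 1 CPM in all libraries of a group, these counts stayed within 1.5 times the reported ones. With 1 library left out they ranged from 93 to 1081, 0 to 191, 0 to 0 and 0 to 1767, and the interaction count was 0 in each fit. In those fits 1 group holds 2 libraries, and the spread is shared with the other groups. A pseudocount was not varied, since the files hold counts.

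With the replicate number as a block, 1489 genes passed in WT neurites against soma and 671 in het neurites against soma. Both fits used all libraries. In het against WT soma, 1300 genes passed in a blocked fit of the soma libraries alone, and 388 passed in that fit without the block. In het against WT neurites the numbers did not pair the libraries, and the libraries numbered 3 did not correlate best with each other. There 891 genes passed in a blocked fit of the neurite libraries alone, and 0 passed in that fit without the block.

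Camera with an estimated correlation called 0 lists in WT, 0 in het, 0 in soma, 0 in neurites and 0 in the interaction. Fry called 2 in WT (nociceptors and translation factors), 0 in het, 0 in soma, 2 in neurites (Schwann cells and satellite glia) and 0 in the interaction. With 1 library left out, camera at the preset correlation called 13 to 18, 11 to 15, 9 to 14, 11 to 17 and 3 to 13. Among results that passed in the main fit or with the library left out, the direction of a list in the camera test turned 7 times. In the interaction without het neurite library 3, ribosomal proteins had a median of -0.017 (range over left-out libraries up to 0.149), satellite glia -0.0295 (from -0.286) and macrophages -0.44 (up to 0.5). Channels had -0.173 there without het neurite library 2 (up to 0.11) and histones -0.146 without WT soma library 3 (up to 0.236). Without WT neurite library 3 the histone median in WT was -0.108 (up to 0.26), and without WT soma library 3 the interferon median in het against WT soma was 0.321 (from -0.296). Over all alternatives, list results kept their side of the threshold, with no call turned, 1463 times. They gained a call 72 times and lost one 78 times, and for named genes these numbers were 4603, 303 and 528. Results that passed in neither fit count as kept, as did all those of named genes in the interaction. In het against WT neurites, named genes kept their side 361 times, gained a call 40 times and lost one 163 times with a library left out. In the fit of the compared libraries alone they kept it 50 times and lost a call 42 times. A change of sign was counted only where the main fit or the alternative passed, so results that passed in neither may have changed sign.

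The correlation of the neurite-to-soma changes of both genotypes was 0.44 without a filter, 0.69 with the filter of at least 1 CPM, 0.43 with DESeq2, 0.77 among genes above the median level, and 0.35 to 0.46 with 1 library left out. That of the het-to-WT changes of both compartments was 0.74 with the filter of at least 1 CPM, 0.51 with DESeq2, 0.81 above the median level, and 0.42 to 0.57 with 1 library left out.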

Other observations

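The tests of the nuclear RNAs and of macrophages against satellite glia, and the choice of the protrusion list, came after the results were seen.

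Rab13, Trak2 and Cdc42bpg, which were among the highest genes in neurites, are known from work on RNAs at the protrusions of migrating cells, and 6 of the 7 other listed members of that group were measured here (Pkp4 was not among the tested genes). Their median log2 fold change was 1.03 in WT neurites against soma and 0.741 in het. Camera at the preset correlation gave p = 5.82e-07 and 2.7e-07 for these, and p = 0.0154 and 0.0135 with an estimated correlation. These p-values belong to a single list and are not adjusted, unlike those of the 27 lists above. Unadjusted, camera with an estimated correlation gave the nociceptor list p = 0.007 in WT and p = 0.0165 in het. In WT, Kif1c, a kinesin gene, had 1.31 ± 0.21 (SE, adjusted p = 0.00541), the collagen receptor gene Ddr2 1.22 ± 0.16 (0.00382), Kank2 1.05 ± 0.12 (0.00253) and Cyb5r3 1.01 ± 0.17 (0.00694), while Net1 had 0.30 ± 0.22 (0.496) and Dynll2 -0.02 ± 0.16 (0.959). A wider set of protrusion RNAs is a candidate explanation for the rise of the 3 genes. Ddr2 and Kank2 also fell in het against WT neurites (-0.81 ± 0.15, adjusted p = 0.0223, and -0.94 ± 0.12, adjusted p = 0.01), as the glial lists did, so the cells that held these RNAs stay open.

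Proliferation and glial genes lay lower in het than in WT cultures. In soma, macrophage genes set against satellite glia genes moved up in het by 2.39 pooled SD. This pair of lists was chosen after their values were seen, so it cannot decide whether the share of all non-neuronal cells fell alike in soma. Neurites were not tested in this way. The soma scores of Schwann cells, fibroblasts and endothelium moved by -2.39, -1.05 and -1.25 pooled SD. The satellite glia score alone moved by -5.34 pooled SD and the macrophage score by 0.66, with its highest value in het soma library 3 (0.958). Without that library the macrophage median was -0.07 (camera at the preset correlation, adjusted p = 0.947). Proliferation genes set against satellite glia genes moved by -1.1 pooled SD, which leaves open whether a lower share of glia alone could set their fall. Genes of like transcript length and GC content did not share the fall. In the blocked fit the trend of all genes on both had an r2 of 0.006, and without it 99.6% of the median of the proliferation list was left, which argues against such a trend as the whole of it. Genotype and a different share of dividing cells at plating both stay open.

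RNAs described as staying in the nucleus of neurons were present in every neurite library. In the neurite library with the least of them, WT neurite library 1, the median of Meg3, Miat, Rian, Mirg and Snhg11 was 37.7% of the mean soma level, and it was 55.4%, 82.2%, 89.4%, 79.7% and 38.8% in the other 5. Cell bodies or nuclei of neurons in the neurite fraction may account for this. These RNAs were taken to be enriched in neurons, which was not measured here. Only if that holds does the same 37.7% argue against glial nuclei alone. RNA with the make-up of the whole soma fraction, if present in the neurite fraction, would make the neurite-to-soma differences smaller. How far this held here was not tested. Neurite and soma libraries of the same genotype correlated at 0.97 to 0.99 in log2 CPM, and libraries within a group at 0.97 to 0.991. Malat1, also a nuclear RNA, stood between 54.5% (het neurite library 3) and 117.9% (WT neurite library 3) of the mean soma level.

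Each comparison has 10 splits of its 6 libraries or cultures into 3 and 3, too few for a share under 0.05. As many genes as in the real split passed in 1 of 10 splits in WT neurites against soma (495, highest other 0), 1 in het (102, highest other 0) and 1 in het against WT neurites (523, highest other 343). In het against WT soma and in the interaction it was 10 of 10 splits, as 0 genes passed in each. In WT and het neurites against soma and in het against WT soma, 4 splits part all pairs, and those besides the real one gave 0 genes. In het against WT soma the real split gave 0 too without the block. In other splits a difference between the real groups adds to the spread, so 0 calls there say little. Blocked, the real split of the soma gave 1300 genes and the highest other 0.

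The authors' own comparisons of het with WT called 1499 transcripts in soma (280 higher and 1219 lower, under 1374 gene names) and 993 in neurites (127 higher and 866 lower, under 922 gene names). Their test is not stated.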
